A study of Saccharomyces cerevisiae with 30 samples.

How the data were processed

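The deposited files held the spot intensities of both channels for 30 arrays, the authors' log2 ratio table, and 3 tables of log2 ratios, 1 per medium. The intensity tables gave 6249 probes, of which 10 had no gene name, and 15 genes had more than 1 probe, which left 6224 genes after averaging the probes of a gene. Of these, 5747 matched a locus tag in the RefSeq gene table, which supplied the gene symbols, and the others kept the symbol or systematic name printed in the deposited files. Per the labels, cells were grown at 30 °C in rich raffinose medium to an OD600 of 0.4, 1 sample was kept, and 2 more were moved to glucose or galactose medium for 1 hour. The labels describe extraction and labelling only as standard methods. Scanning, image analysis, background subtraction and the array build are not given in the sources used here.

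The unit of both deposited channel tables was intensity, read from the values, and each table had 6633 blank cells, whose meaning is not given in the sources used here. The authors' ratio table and the authors' 3 tables per medium were in log2, also read from the values and, for the latter, from the deposited header line. That header gives the values as relative to wild type sample 1 in raffinose, and subtracting that array from the ratio table returned the galactose and glucose tables (difference 0.000), while the raffinose table differed by 0.110. The ratio table held 5606 entries with 14 repeated probe IDs, array medians of 0.000, and between 437 and 927 exact zeros per array, which were treated as missing. In raffinose, its mot3 mit1-1 sin4 culture 1 matched the other culture of the raffinose table (median absolute deviation 0.000, against 0.110 for its own). Which is right is open, and the numbers printed in the intensity tables were kept. Reference columns of 2 raffinose arrays shared a name, and the mean of both columns served each of those arrays.

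Per the labels, RNA of the reference strain FY3054 carried Cy3 and RNA of each experimental strain carried Cy5. The values showed the opposite: the median standard deviation of a gene between arrays was 0.37 log2 in the table named Cy3 and 0.11 in the table named Cy5, and SIN4 and GAL1 followed strain and medium in the table named Cy3. The table named Cy3 was therefore taken as the channel of each array's own strain and the other as the reference channel. Each sign below is likely own strain over reference on that basis. Read as named, the sign of every log ratio would turn, and single-channel values would come from the other table. The authors' own ratio, per its values, is the table named Cy3 over the table named Cy5, and its correlation with the ratio used here was 0.75 to 0.98 per array.

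Intensities were corrected with normexp (offset 50) and normalized by loess within arrays in limma 3.58.1 under R 4.3.3, with statmod 1.5.0. For comparisons averaged over media, the 3 arrays of a culture were averaged first, and 10 cultures of 6 strains entered a single limma fit with robust moderation of the variances. Comparisons within a medium and the differences between media used all 30 arrays in 18 strain-by-medium groups. Since 6 of these groups had 1 array and 2 strains had 1 culture, their spread was taken from the other groups. Wild-type media were compared in the own-strain channel after Aquantile scaling between arrays, in case the reference shared their effect. It hardly did (slope 0.104). Values are log2 differences ± the standard error of the fit, and a gene passed at a Benjamini-Hochberg adjusted p under 0.05 over the genes tested in that comparison. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

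Tests not named below as later, gene lists and the naming rule were chosen before the data were examined. The rule names, per strain, the 10 largest increases and 10 largest decreases among genes that passed with the same sign in every culture, the 4 largest members of each list called by camera, and the genes GAL1, GAL2, GAL3, GAL7, GAL10, GAL80, HIS3, URA3, SIN4, MOT3, GRR1 and MIT1. For contrasts within a medium, between media and between the triple mutants it names the 5 largest in each direction, and not every gene it covers is printed. Genes outside it are said to be so. The 34 lists were tested with camera at a preset correlation of 0.01, then with an estimated correlation, with fry as a further test, and adjusted over the lists of a comparison. The lists were COS family and other subtelomeric multigene families, MATa-specific genes (cell type), MATalpha-specific genes (cell type), Mediator head and middle subunits, Mediator kinase module, Mediator tail subunits, TCA cycle and respiratory chain, amino acid biosynthesis, amino acid permeases and SPS sensing, auxotrophic marker and reporter genes, cell cycle G1/S (CLN and SBF/MBF targets), cell wall integrity and cell wall proteins, core histones, cytosolic ribosomal proteins, ergosterol synthesis, flocculation and filamentous growth, galactose regulon, general stress response, glucose-repressed carbon metabolism, glycolysis and fermentation, haploid-specific genes (cell type), hexose transporters and glucose sensing, hypoxic and anaerobic genes, iron regulon, meiosis and sporulation (cell type), methionine and sulfur assimilation, mutated genes named in the strain labels, nitrogen catabolite-repressed genes, pheromone response and mating, phosphate regulon, ribosome biogenesis, seripauperin (PAU) family, thiamine synthesis, and trehalose and glycogen metabolism. List counts give members that passed over all genes tested, and counts adjusted over the list alone name higher members before lower ones.

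Pairing by culture holds within a strain, because the labels say that 1 raffinose culture was split. Residuals of the media of a culture correlated between -0.11 and 0.39, and 6 of 12 values were over 0.1, so contrasts of media were repeated with the culture as a block. In simulated data made from these arrays with 5600 genes, of which 67 changed by 0.5 log2, the fit recovered 82.1% of them for mutant 1.2 and 79.1% for mutant 2.3a (1 culture each). The shares were 95.5% for mutant 2.3b, 97.0% for mot3 grr1-1 sin4 and 94.0% for mot3 mit1-1 sin4 (2 cultures each), and false calls numbered 8 to 17.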

Results

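The series measured transcript levels in budding yeast on 2-colour arrays, with the RNA of a strain in 1 channel and wild-type reference RNA in the other. Its title concerns mutants in which transcription can be activated over a long distance. The 30 arrays covered 6 strains in 3 media. Wild type (FY3054), mutant 2.3b, mot3 grr1-1 sin4 and mot3 mit1-1 sin4 each had 2 cultures and 6 arrays, and mutants 1.2 and 2.3a each had 1 culture and 3 arrays. These numbers follow the sample titles, whereas the design text gives mutant 2.3b a single replicate but then names a sample of mutant 2.3a. The labels do not give the mutations carried by mutants 1.2, 2.3a and 2.3b. Median intensity per array ran from 795 to 2978 in the own-strain channel and from 612 to 2084 in the reference channel, and 67 to 535 spots per array were blank. The number of arrays limits the precision of every value. Culture means of the same strain correlated across genes at r = 0.93 to 0.98, where genes are not independent replicates.

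The strain labels name SIN4 (YNL236W), which encodes a subunit of the Mediator tail, MOT3 (YMR070W), a zinc-finger transcription factor, GRR1, the F-box protein of a ubiquitin ligase that acts in glucose sensing, and MIT1, a regulator of filamentous growth. These values ask whether the arrays carry the label mutations, although an allele need not change its own transcript. SIN4 was low in every mutant: its log2 ratio lay between -4.30 and -3.49 on all mutant arrays and between 0.09 and 0.28 on wild-type arrays (likely own strain over reference, from the behaviour of the channels). Against wild type SIN4 changed by -4.00 ± 0.08 (SE) in mutant 1.2, -4.06 ± 0.08 in mutant 2.3a, -4.16 ± 0.07 in mutant 2.3b, -3.98 ± 0.07 in mot3 grr1-1 sin4 and -4.14 ± 0.07 in mot3 mit1-1 sin4 (largest adjusted p = 3.38e-08). MOT3 passed in all 5 strains, at -1.35 ± 0.09, -0.76 ± 0.09, -1.15 ± 0.07, -0.81 ± 0.07 and -0.28 ± 0.07 in the same order. In mot3 mit1-1 sin4 (adjusted p = 0.0330) MOT3 no longer passed without its own culture 1 or culture 2, with values between -0.317 and -0.239 over the cultures left out. GRR1 was lower in mot3 grr1-1 sin4 (-0.23 ± 0.05) and in mutant 1.2 (-0.26 ± 0.07, larger adjusted p = 0.0106). It did not pass without mot3 grr1-1 sin4 culture 1 (-0.200) in the former, or without wild type culture 2 (-0.237) in the latter. MIT1 was lower in mot3 mit1-1 sin4 (-0.63 ± 0.10), mutant 2.3a (-0.66 ± 0.12) and mutant 2.3b (-0.58 ± 0.10, largest adjusted p = 0.0055).

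Mutant 1.2 against wild type, averaged over the 3 media, asks which transcripts differ in this isolate whatever the carbon source. Of the genes with the largest increases, TSA2 encodes a peroxiredoxin, TRX2 a thioredoxin, GTT2 a glutathione transferase, HBN1 a putative nitroreductase, AAD4 an aryl-alcohol dehydrogenase and FLR1 a drug exporter. LEU2, an enzyme of leucine synthesis that often serves as a marker gene, was also far higher. Among the largest decreases were the amino acid permease genes BAP3, TAT1 and GNP1, the serine deaminase gene CHA1, the mitotic cyclin gene CLB1, and CYT1, which encodes cytochrome c1. The alpha-factor gene MF(ALPHA)1 fell as well. Increases were TSA2 (6.75 ± 0.10 log2), LEU2 (6.66 ± 0.10), AAD4 (5.38 ± 0.09), GTT2 (5.31 ± 0.10), YCT1 (5.24 ± 0.11), DSF1 (5.15 ± 0.16), YML131W (5.08 ± 0.15), FLR1 (5.07 ± 0.10), TRX2 (4.93 ± 0.19) and HBN1 (4.91 ± 0.14). Decreases were BAP3 (-4.76 ± 0.09), TAT1 (-4.33 ± 0.11), ARO9 (-3.24 ± 0.14), CHA1 (-3.12 ± 0.11), PHO3 (-3.09 ± 0.19), GNP1 (-2.90 ± 0.19), CYT1 (-2.77 ± 0.16), CLB1 (-2.57 ± 0.13) and MF(ALPHA)1 (-2.53 ± 0.08), with largest adjusted p = 7.68e-06 among these genes. Of 5770 genes tested, 3419 passed, 1800 higher and 1619 lower, a split that turned to 1189 and 1609 with the authors' tables and 1748 and 1802 with median centring. Mutant 1.2 had 1 culture, so its own spread could not be measured.

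Respiration, ribosome production and nitrogen use differed as groups in mutant 1.2, though not with an estimated correlation. Of 48 genes of the TCA cycle and respiratory chain, 2 were higher, 43 lower and 3 did not pass (2 and 44 adjusted over the list alone, camera adjusted p = 5.53e-16, adjusted p = 0.2995 with an estimated correlation). Besides CYT1, ACO1 (-2.51 ± 0.14), RIP1 (-2.38 ± 0.16) and QCR7 (-2.35 ± 0.10) showed the largest changes in that list. Cytosolic ribosomal protein genes moved the same way: of 137, 4 were higher, 109 lower and 24 did not pass (4 and 114 adjusted over the list alone, camera adjusted p = 5.42e-15, adjusted p = 0.320 with an estimated correlation). Of 46 ribosome biogenesis genes, 0 were higher, 42 lower and 4 did not pass (0 and 43 adjusted over the list alone, camera adjusted p = 1.05e-10, adjusted p = 0.328 with an estimated correlation). Genes that nitrogen catabolite repression keeps low on rich nitrogen sources were higher, among them DAL7 (3.92 ± 0.09), MEP2 (3.28 ± 0.10), PUT4 (3.19 ± 0.10) and GAP1 (2.53 ± 0.10), which serve the use of allantoin, ammonium, proline and other amino acids. Of 21 in that list, 20 were higher, 1 lower and 0 did not pass (20 and 1 adjusted over the list alone, camera adjusted p = 5.85e-08, adjusted p = 0.210 with an estimated correlation). Of 28 general stress genes, 26 were higher, 0 lower and 2 did not pass (28 and 0 adjusted over the list alone, camera adjusted p = 3.30e-07, adjusted p = 0.313 with an estimated correlation). All members of the PAU family of anaerobic cell wall proteins passed: of 24, 24 were higher, 0 lower and 0 did not pass (24 and 0 adjusted over the list alone, camera adjusted p = 6.40e-13, adjusted p = 0.2998 with an estimated correlation). Of 30 genes in the COS and other subtelomeric families, 28 were higher, 0 lower and 2 did not pass (28 and 0 adjusted over the list alone, camera adjusted p = 7.32e-12, adjusted p = 0.210 with an estimated correlation). Of 22 iron regulon genes, 16 were higher, 1 lower and 5 did not pass (16 and 1 adjusted over the list alone, camera adjusted p = 0.0016, adjusted p = 0.557 with an estimated correlation). Of 17 thiamine genes, 14 were higher, 1 lower and 2 did not pass (14 and 1 adjusted over the list alone, camera adjusted p = 7.16e-04, adjusted p = 0.2998 with an estimated correlation). Of 25 G1/S cell cycle genes, 0 were higher, 19 lower and 6 did not pass (0 and 19 adjusted over the list alone, camera adjusted p = 2.39e-06, adjusted p = 0.2998 with an estimated correlation).

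Further lists called in mutant 1.2 included glucose-repressed carbon metabolism, of which 27 genes were measured and 20 were higher, 1 lower and 6 did not pass (20 and 1 adjusted over the list alone, camera adjusted p = 9.90e-05, adjusted p = 0.2998 with an estimated correlation). Of 16 phosphate genes, 1 were higher, 10 lower and 5 did not pass (1 and 11 adjusted over the list alone, camera adjusted p = 0.0049, adjusted p = 0.313 with an estimated correlation). Called higher were amino acid synthesis (26 higher and 9 lower of 46) and sulfur assimilation (16 higher and 2 lower of 22). So were the hypoxic genes (15 higher and 1 lower of 21) and storage carbohydrates (17 higher and 1 lower of 20). Glycolysis was called higher and pheromone response lower, but their medians, 0.47 and -0.185, turned to -0.206 and 0.032 with median centring. None of the 21 calls in this strain held with an estimated correlation (adjusted p from 0.210 to 0.557), which has little power here. Lists that camera never called in any comparison were the Mediator kinase module, where of 4 genes in mutant 1.2 0 were higher, 0 lower and 4 did not pass (0 and 0 adjusted over the list alone, camera adjusted p = 0.596), and flocculation and filamentous growth, where of 17 genes 7 were higher, 6 lower and 4 did not pass (8 and 7 adjusted over the list alone, camera adjusted p = 0.292).

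Mutant 2.3a against wild type, averaged over media, asks the same of a different isolate. Cell-type genes were prominent. The alpha-factor genes MF(ALPHA)1 and MF(ALPHA)2 and the a-factor receptor gene STE3, all expressed in alpha cells, fell, and the a-factor exporter gene STE6, expressed in a cells, rose. Of the other genes, MEP2 imports ammonium, SUL2 sulfate and PUT4 proline, and these rose, while the permease genes BAP3, TAT1, GNP1 and PTR2 fell. FLO11, which encodes a cell surface flocculin, was higher. Increases were LEU2 (5.84 ± 0.10 log2), STE6 (3.59 ± 0.10), FLO11 (3.48 ± 0.20), YBR012C (3.46 ± 0.14), SER3 (3.28 ± 0.12), MEP2 (3.11 ± 0.10), SUL2 (3.09 ± 0.13), MET16 (2.86 ± 0.17), PUT4 (2.82 ± 0.10) and YCT1 (2.73 ± 0.11). Decreases were MF(ALPHA)1 (-5.96 ± 0.08), BAP3 (-5.31 ± 0.09), STE3 (-4.55 ± 0.08), MF(ALPHA)2 (-4.09 ± 0.18), TAT1 (-4.00 ± 0.11), CHA1 (-3.62 ± 0.11), GNP1 (-3.37 ± 0.19), GCV1 (-3.17 ± 0.35) and PTR2 (-2.94 ± 0.08), with largest adjusted p = 4.23e-04. LEU2 and CHA1 lie on chromosome III, whose genes in mutant 2.3a had a median of 0.827 log2 (1.77-fold), with 129 higher and 6 lower of 149 tested. On every other chromosome the median lay between -0.035 and 0.013. Of 5729 genes tested, 1367 passed, 837 higher and 530 lower, or 572 and 515 with the authors' tables, and the count fell to 836 without wild type culture 1 and 798 without culture 2.

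Among lists, sulfur assimilation and nitrogen use stood out in mutant 2.3a. Of 22 methionine and sulfur genes, 18 were higher, 0 lower and 4 did not pass (19 and 1 adjusted over the list alone, camera adjusted p = 2.64e-13, adjusted p = 0.141 with an estimated correlation), with STR3 (2.61 ± 0.15) and MET14 (2.54 ± 0.16) beside SUL2 and MET16. Of 22 nitrogen catabolite genes, 17 were higher, 1 lower and 4 did not pass (18 and 2 adjusted over the list alone, camera adjusted p = 2.96e-12, adjusted p = 0.137 with an estimated correlation). Of 48 TCA cycle and respiratory genes, 0 were higher, 33 lower and 15 did not pass (0 and 38 adjusted over the list alone, camera adjusted p = 4.37e-14, adjusted p = 0.169 with an estimated correlation). The glycolytic genes PDC6 (2.55 ± 0.14) and PGK1 (1.87 ± 0.10) were higher, the latter on chromosome III. The MATalpha-specific list, of 6 genes, had 1 higher and 5 lower (1 and 5 adjusted over the list alone, camera adjusted p = 6.02e-07, adjusted p = 0.141 with an estimated correlation). Of 4 MATa-specific genes, 4 were higher, 0 lower and 0 did not pass (4 and 0 adjusted over the list alone, camera adjusted p = 0.0024, adjusted p = 0.141 with an estimated correlation). BAR1 (3.81 ± 0.11) and ASG7 (2.34 ± 0.08) had the largest changes there. Of 20 hypoxic genes, 13 were higher, 1 lower and 6 did not pass (14 and 1 adjusted over the list alone, camera adjusted p = 1.16e-05, adjusted p = 0.137 with an estimated correlation), with ANB1, a translation factor gene used under low oxygen, at 2.31 ± 0.10. Of 21 hexose transporter and glucose sensing genes, 10 were higher, 1 lower and 10 did not pass (11 and 2 adjusted over the list alone, camera adjusted p = 0.0058, adjusted p = 0.274 with an estimated correlation). Of 22 amino acid permease and sensing genes, 5 were higher, 8 lower and 9 did not pass (6 and 9 adjusted over the list alone, camera adjusted p = 0.0144, adjusted p = 0.514 with an estimated correlation). Of 46 amino acid synthesis genes, 26 were higher, 4 lower and 16 did not pass (28 and 4 adjusted over the list alone, camera adjusted p = 4.50e-08, adjusted p = 0.169 with an estimated correlation). The marker and reporter list was called higher (adjusted p = 0.0203, adjusted p = 0.169 with an estimated correlation), with 4 higher and 1 lower of 8 and 4 and 1 adjusted over the list alone. Of 6 Mediator tail genes, 0 were higher, 2 lower and 4 did not pass (0 and 2 adjusted over the list alone, camera adjusted p = 0.0215, adjusted p = 0.169 with an estimated correlation), with SIN4 the largest.

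Mutant 2.3b against wild type, averaged over media, had 2 cultures on each side and showed nearly the same leading genes as mutant 2.3a. The alpha-cell genes MF(ALPHA)1, MF(ALPHA)2 and STE3 fell and STE6 rose. The ammonium transporter gene MEP2 and the flocculin gene FLO11 rose, as did CIT2, which encodes the peroxisomal citrate synthase. YHB1, which encodes a nitric oxide oxidoreductase, fell together with several permease genes. Increases were LEU2 (6.56 ± 0.08 log2), MEP2 (4.22 ± 0.08), FLO11 (4.15 ± 0.16), YBR012C (3.97 ± 0.12), STE6 (3.78 ± 0.08), CIT2 (3.32 ± 0.07), SER3 (3.10 ± 0.10), SUL2 (3.08 ± 0.11), PUT4 (2.86 ± 0.08) and MET14 (2.76 ± 0.13). Decreases were MF(ALPHA)1 (-6.50 ± 0.06), BAP3 (-5.44 ± 0.07), TAT1 (-4.63 ± 0.09), STE3 (-4.62 ± 0.06), MF(ALPHA)2 (-3.93 ± 0.15), GNP1 (-3.76 ± 0.15), CHA1 (-3.53 ± 0.09), YHB1 (-3.47 ± 0.16) and PTR2 (-3.41 ± 0.07), with largest adjusted p = 2.57e-06. Chromosome III, which carries LEU2, CIT2 and CHA1, had a median of 0.870 log2 (1.83-fold), with 134 genes higher and 6 lower of 155 tested, and the other chromosomes had medians from -0.039 to 0.032. Of 5810 genes tested, 2512 passed, 1305 higher and 1207 lower, or 924 and 1171 with the authors' tables, and the count was 1588 without wild type culture 1.

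Nearly the whole respiratory list was lower in mutant 2.3b. Of 48 TCA cycle and respiratory genes, 1 were higher, 46 lower and 1 did not pass (1 and 46 adjusted over the list alone, camera adjusted p = 2.91e-22, adjusted p = 0.171 with an estimated correlation). Glycolysis was called in the other direction: of 25 genes, 20 were higher, 3 lower and 2 did not pass (20 and 3 adjusted over the list alone, camera adjusted p = 3.38e-07, adjusted p = 0.235 with an estimated correlation). PGK1 (2.19 ± 0.08), PDC6 (2.11 ± 0.12), ADH5 (1.63 ± 0.07) and GPM1 (1.38 ± 0.07) were among its largest changes, of which PGK1 lies on chromosome III. Of 46 ribosome biogenesis genes, 0 were higher, 36 lower and 10 did not pass (0 and 39 adjusted over the list alone, camera adjusted p = 3.03e-09, adjusted p = 0.484 with an estimated correlation). Of 22 methionine and sulfur genes, 19 were higher, 2 lower and 1 did not pass (19 and 2 adjusted over the list alone, camera adjusted p = 6.04e-10, adjusted p = 0.171 with an estimated correlation). Of 22 nitrogen catabolite genes, 19 were higher, 2 lower and 1 did not pass (19 and 2 adjusted over the list alone, camera adjusted p = 2.00e-09, adjusted p = 0.171 with an estimated correlation). Of 6 MATalpha-specific genes, 1 were higher, 5 lower and 0 did not pass (1 and 5 adjusted over the list alone, camera adjusted p = 1.80e-05, adjusted p = 0.171 with an estimated correlation), and of 4 MATa-specific genes, 4 were higher, 0 lower and 0 did not pass (4 and 0 adjusted over the list alone, camera adjusted p = 0.0084, adjusted p = 0.171 with an estimated correlation). BAR1 (3.86 ± 0.10) and ASG7 (2.42 ± 0.07) were among its largest changes. Of 29 cell wall genes, 5 were higher, 14 lower and 10 did not pass (5 and 14 adjusted over the list alone, camera adjusted p = 0.0132, adjusted p = 0.557 with an estimated correlation). ERG28 of ergosterol synthesis stood at 1.16 ± 0.08. Of 20 storage carbohydrate genes, 3 were higher, 7 lower and 10 did not pass (3 and 7 adjusted over the list alone, camera adjusted p = 0.0249, adjusted p = 0.686 with an estimated correlation).

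**Figure D1:**
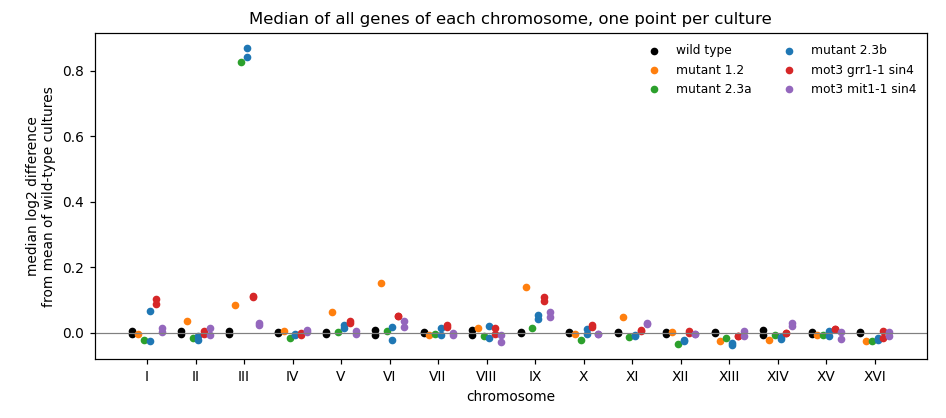
Each point is the median log2 difference from the mean of the wild-type cultures (vertical axis) over the genes of a chromosome (horizontal axis) in 1 culture, coloured by strain. Chromosome III lies apart in mutants 2.3a and 2.3b, whose strain medians are 0.827 and 0.870.

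The strain mot3 grr1-1 sin4, in which the label mutations are combined, was compared with wild type to see what they change together. LEU2, the flocculin gene FLO11, DSF1 and the proline permease gene PUT4 led the increases. Further down were ANB1, a low-oxygen form of translation factor eIF5A, the ammonium permease gene MEP2, TIR4 of a cell wall protein family, and DFP4. Several amino acid permease genes that the SPS sensor controls (BAP2, BAP3, TAT1 and GNP1) were lower, as were GCV1 of glycine cleavage, CHA1 and ARO9 of amino acid breakdown, and YHB1. Increases were LEU2 (6.23 ± 0.08 log2), FLO11 (4.23 ± 0.16), DSF1 (4.08 ± 0.13), PUT4 (3.91 ± 0.08), YBR012C (3.87 ± 0.12), ANB1 (3.79 ± 0.08), TIR4 (3.26 ± 0.12), MEP2 (3.20 ± 0.08), COS12 (2.92 ± 0.32) and DFP4 (2.88 ± 0.10). Decreases were BAP3 (-5.13 ± 0.07), TAT1 (-4.00 ± 0.09), GCV1 (-3.46 ± 0.29), CHA1 (-3.44 ± 0.09), YHB1 (-3.10 ± 0.16), ARO9 (-3.09 ± 0.11), PHO3 (-3.03 ± 0.16), GNP1 (-2.93 ± 0.15) and BAP2 (-2.57 ± 0.16), with largest adjusted p = 2.44e-04. Of 5811 genes tested, 2489 passed, 1417 higher and 1072 lower. With the authors' tables the split was 965 higher and 1133 lower, and the count was 1589 without mot3 grr1-1 sin4 culture 2 and 1510 without wild type culture 1.

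Groups that changed in mot3 grr1-1 sin4 included the respiratory genes, of which 48 were measured and 2 were higher, 44 lower and 2 did not pass (3 and 45 adjusted over the list alone, camera adjusted p = 3.32e-16, adjusted p = 0.172 with an estimated correlation). Of 21 hypoxic genes, 16 were higher, 1 lower and 4 did not pass (16 and 1 adjusted over the list alone, camera adjusted p = 8.50e-07, adjusted p = 0.146 with an estimated correlation). Of 24 PAU genes, 22 were higher, 0 lower and 2 did not pass (22 and 0 adjusted over the list alone, camera adjusted p = 2.30e-13, adjusted p = 0.262 with an estimated correlation). Of 30 COS and other subtelomeric genes, 25 were higher, 0 lower and 5 did not pass (25 and 1 adjusted over the list alone, camera adjusted p = 7.41e-11, adjusted p = 0.146 with an estimated correlation). Of 22 sulfur genes, 20 were higher, 0 lower and 2 did not pass (20 and 0 adjusted over the list alone, camera adjusted p = 6.32e-11, adjusted p = 0.172 with an estimated correlation). Of 22 nitrogen catabolite genes, 18 were higher, 1 lower and 3 did not pass (18 and 1 adjusted over the list alone, camera adjusted p = 3.87e-09, adjusted p = 0.161 with an estimated correlation). Of 27 glucose-repressed genes, 16 were higher, 3 lower and 8 did not pass (17 and 3 adjusted over the list alone, camera adjusted p = 0.0094, adjusted p = 0.496 with an estimated correlation), with SUC2, the invertase gene, at 2.15 ± 0.07 and MDH2 at -1.81 ± 0.11. Of 6 MATalpha-specific genes, 0 were higher, 6 lower and 0 did not pass (0 and 6 adjusted over the list alone, camera adjusted p = 8.15e-05, adjusted p = 0.205 with an estimated correlation). MF(ALPHA)1 stood at -1.58 ± 0.06. Of 16 phosphate genes, 1 were higher, 10 lower and 5 did not pass (1 and 11 adjusted over the list alone, camera adjusted p = 6.12e-04, adjusted p = 0.262 with an estimated correlation), with PHO5, a secreted acid phosphatase, at -2.28 ± 0.17. Of 9 core histone genes, 1 were higher, 6 lower and 2 did not pass (1 and 6 adjusted over the list alone, camera adjusted p = 0.0083, adjusted p = 0.172 with an estimated correlation).

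The strain mot3 mit1-1 sin4 asks the same question with mit1-1 in place of grr1-1. LEU2 rose, as in every mutant. LEU1 of leucine synthesis, the branched-chain aminotransferase gene BAT1 and the mitochondrial carrier gene OAC1 fell. ANB1 and AAC3, both used under low oxygen, rose with the proline permease gene PUT4 and the flocculin gene FLO11. HPF1 and CSS1, which encode cell surface proteins, and the reductase gene GRE2 fell. Increases were LEU2 (4.01 ± 0.08 log2), DSF1 (3.72 ± 0.13), PUT4 (3.34 ± 0.08), ANB1 (3.32 ± 0.08), FLO11 (3.02 ± 0.16), YBR012C (2.52 ± 0.12), DFP4 (2.51 ± 0.10), HSP26 (2.37 ± 0.23), AAC3 (2.21 ± 0.10) and MET28 (2.18 ± 0.09). Decreases were HPF1 (-2.98 ± 0.13), CHA1 (-2.76 ± 0.09), LEU1 (-2.56 ± 0.14), CSS1 (-2.11 ± 0.07), OAC1 (-2.01 ± 0.07), GRE2 (-1.74 ± 0.16), BAT1 (-1.61 ± 0.07), ECM13 (-1.52 ± 0.10) and IZH4 (-1.50 ± 0.21), with largest adjusted p = 0.0022. Of 5792 genes tested, 1102 passed, 660 higher and 442 lower, or 432 and 429 with the authors' tables. Single cultures decided much of that count, which was 676 without mot3 mit1-1 sin4 culture 2, 501 without wild type culture 1 and 471 without wild type culture 2.

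Among the lists in mot3 mit1-1 sin4, 16 phosphate genes were measured and 12 were higher, 1 lower and 3 did not pass (13 and 2 adjusted over the list alone, camera adjusted p = 3.99e-04, adjusted p = 0.313 with an estimated correlation). Of 46 amino acid synthesis genes, 5 were higher, 20 lower and 21 did not pass (7 and 24 adjusted over the list alone, camera adjusted p = 6.23e-05, adjusted p = 0.342 with an estimated correlation). Of 24 PAU genes, 21 were higher, 0 lower and 3 did not pass (21 and 0 adjusted over the list alone, camera adjusted p = 4.13e-14, adjusted p = 0.313 with an estimated correlation). Of 21 hypoxic genes, 12 were higher, 1 lower and 8 did not pass (13 and 2 adjusted over the list alone, camera adjusted p = 6.84e-05, adjusted p = 0.279 with an estimated correlation). Of 22 nitrogen catabolite genes, 10 were higher, 2 lower and 10 did not pass (11 and 2 adjusted over the list alone, camera adjusted p = 3.38e-04, adjusted p = 0.313 with an estimated correlation). The respiratory list was called higher here: of 48, 14 were higher, 4 lower and 30 did not pass (18 and 5 adjusted over the list alone, camera adjusted p = 0.0231, adjusted p = 0.613 with an estimated correlation), although IDH2 was at -0.61 ± 0.08. Of 25 glycolysis genes, 12 were higher, 3 lower and 10 did not pass (15 and 3 adjusted over the list alone, camera adjusted p = 6.54e-04, adjusted p = 0.462 with an estimated correlation).

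**Figure D2:**
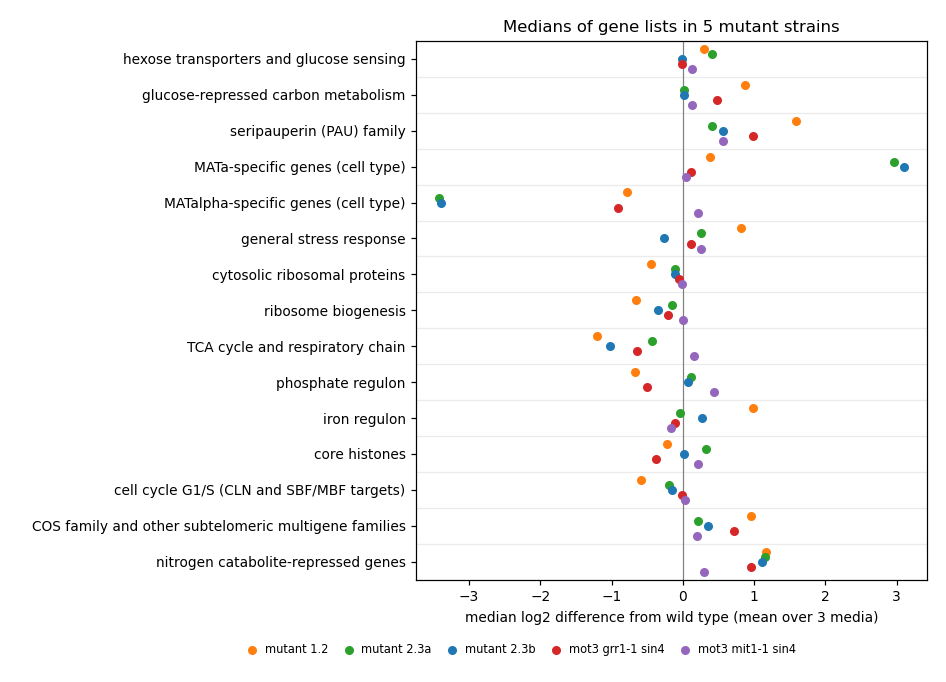
Each point is the median log2 difference from wild type (horizontal axis, mean over 3 media) of the measured members of a gene list (vertical axis) in 1 of 5 mutant strains. The MATa and MATalpha lists lie far from 0 in mutants 2.3a and 2.3b, and the TCA cycle and respiratory list lies at -1.21 in mutant 1.2, -1.02 in mutant 2.3b and 0.15 in mot3 mit1-1 sin4.

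The triple mutants share mot3 and sin4 on their labels, so their direct comparison (mot3 grr1-1 sin4 over mot3 mit1-1 sin4) asks what differs between grr1-1 and mit1-1. Among the largest differences, MEP2 for ammonium and SAM3 for S-adenosylmethionine were higher with grr1-1, while BAP3, TAT1, the phosphatase gene PHO5 and the glycerophosphoinositol transporter gene GIT1 were lower. Increases were MEP2 (2.85 ± 0.08 log2), TIR4 (2.47 ± 0.12), STR3 (2.41 ± 0.12), SAM3 (2.25 ± 0.07) and LEU2 (2.21 ± 0.08), and decreases were BAP3 (-4.90 ± 0.07), TAT1 (-3.87 ± 0.09), PHO5 (-3.15 ± 0.17), GIT1 (-2.92 ± 0.09) and YHB1 (-2.81 ± 0.16), with largest adjusted p = 1.80e-05. GRR1 differed by -0.35 ± 0.05 (adjusted p = 0.0016) and MOT3 by -0.53 ± 0.07 (adjusted p = 9.52e-04), and GAL1 was higher with grr1-1 by 0.61 ± 0.11 (adjusted p = 0.0031). Of 17 phosphate genes, 0 were higher, 17 lower and 0 did not pass (0 and 17 adjusted over the list alone, camera adjusted p = 5.00e-10, adjusted p = 0.102 with an estimated correlation). Of 48 TCA cycle and respiratory genes, 3 were higher, 44 lower and 1 did not pass (3 and 44 adjusted over the list alone, camera adjusted p = 6.84e-19, adjusted p = 0.134 with an estimated correlation). Of 9 core histone genes, 0 were higher, 9 lower and 0 did not pass (0 and 9 adjusted over the list alone, camera adjusted p = 3.90e-06, adjusted p = 0.102 with an estimated correlation). Of 46 amino acid synthesis genes, 33 were higher, 3 lower and 10 did not pass (33 and 3 adjusted over the list alone, camera adjusted p = 2.86e-09, adjusted p = 0.134 with an estimated correlation). Of 24 ergosterol genes, 14 were higher, 1 lower and 9 did not pass (14 and 1 adjusted over the list alone, camera adjusted p = 1.03e-04, adjusted p = 0.102 with an estimated correlation). Of 25 pheromone response genes, 3 were higher, 13 lower and 9 did not pass (4 and 13 adjusted over the list alone, camera adjusted p = 1.68e-04, adjusted p = 0.102 with an estimated correlation). Of 5890 genes tested, 2330 passed, 1276 higher and 1054 lower, and the count was 1412 without mot3 grr1-1 sin4 culture 1 and 1427 without its culture 2.

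Across genes, the log2 differences of the mutants were correlated with each other over 5712 genes tested in every strain. Genes are not independent replicates, and because all strains share the wild-type arrays, simulated strains without any change also correlate. The simulated r is that of noise alone, so it is no yardstick for strains that do change. The covariances below can be compared with simulation more directly. Mutants 2.3a and 2.3b were closest, with r = 0.910 against 0.411 in simulation, followed by mutant 2.3b and mot3 grr1-1 sin4 (0.749 against 0.5) and mutant 2.3a and mot3 grr1-1 sin4 (0.721 against 0.409). Mutant 1.2 and mot3 grr1-1 sin4 gave 0.618 against 0.412, and the triple mutants gave 0.6 against 0.506. Values for mutant 1.2 and mot3 mit1-1 sin4 (0.398 against 0.412) and mutant 2.3b and mot3 mit1-1 sin4 (0.445 against 0.503) were not above simulation. Their covariances were, at 0.0940 and 0.0736 against 0.0037 each, and 439 and 379 genes were higher in both strains, where independent calls would share 203 and 147. The covariance of mutants 2.3a and 2.3b was 0.2211 against 0.0037 simulated, and of their calls 737 genes were higher in both, 455 lower in both and 12 opposite, where independent calls would share 189 and 111. In all 5 strains together, 230 genes were higher and 90 lower. The controls were not divided between strains, so part of the excess can come from shared controls.

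Each mutant was also compared with wild type within each medium, to see which differences belong to a carbon source. In galactose, the largest increases included DSF1 (a mannitol dehydrogenase homologue) and HXT15 and HXT16 (hexose transporter family) in mutant 1.2 (6.40 ± 0.29, 6.29 ± 0.51 and 6.36 ± 0.23) and DSF1, MAN2 and HXT15 in mot3 mit1-1 sin4 (5.29 ± 0.24, 5.11 ± 0.26 and 4.73 ± 0.41). STE2, the alpha-factor receptor gene of a cells, was higher in mutants 2.3a and 2.3b, by 5.08 ± 0.21 and 4.54 ± 0.17 in galactose and 5.30 ± 0.21 and 5.19 ± 0.17 in raffinose. In glucose, BAR1, the a-cell protease gene, was higher in mutant 2.3a (4.05 ± 0.17) and mutant 2.3b (4.29 ± 0.14). There too, PHO3 was lower in mutant 1.2 (-4.82 ± 0.33) and mot3 grr1-1 sin4 (-5.02 ± 0.27), and the polyamine exporter gene TPO2 was lower in mot3 grr1-1 sin4 (-4.18 ± 0.25) and mot3 mit1-1 sin4 (-2.95 ± 0.25). In raffinose, SRX1, which encodes sulfiredoxin, led in mutant 1.2 (5.91 ± 0.17), and HPF1 and CSS1 fell in mot3 mit1-1 sin4 (-4.41 ± 0.26 and -3.23 ± 0.12). Within a medium, the largest of the adjusted p values of these genes was 9.68e-07.

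Genes that passed in galactose, glucose and raffinose numbered 3209, 2558 and 2135 in mutant 1.2, where no culture moved a count by more than 1.5 times. They numbered 928, 898 and 1745 in mutant 2.3a. Without wild type culture 1 these were 537, 484 and 1120, without culture 2 they were 560, 555 and 1011, and without either culture of mutant 2.3b the glucose count was 1424. In mutant 2.3b the counts were 2062, 1533 and 1953, which became 1135, 803 and 1163 without wild type culture 1, with 1336 in galactose and 878 in glucose without culture 2. In mot3 grr1-1 sin4 they were 2073, 1714 and 1944. These fell to 1247, 1077 and 1057 without its own culture 1, 1279, 885 and 1139 without its own culture 2, 1271, 878 and 1074 without wild type culture 1, and 1249, 1076 and 1257 without wild type culture 2. In mot3 mit1-1 sin4 they were 1139, 675 and 1002, and became 548, 386 and 575 without its own culture 2, 442, 268 and 416 without wild type culture 1, and 482, 273 and 484 without wild type culture 2. Without either culture of mutant 2.3b, they were 1743, 1162 and 1540.

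Whether a strain's difference from wild type depends on the carbon source was tested as galactose minus glucose, for the strains with 2 cultures. In mutant 2.3b, the MATalpha-specific and glycolysis lists were called relatively higher in galactose and the respiratory list relatively lower. None of these calls held with the culture as a block and an estimated correlation (adjusted p = 0.178, adjusted p = 0.0807 and adjusted p = 0.188). In wild type itself, TPO2 (-4.86) and 5 of 6 MATalpha-specific genes were lower in galactose than in glucose. TPO2, PUT4 and HXT6 (hexose import) were relatively higher, and DIP5 (acidic amino acid permease) and PYC1 (pyruvate carboxylase) relatively lower. Values were TPO2 (3.45 ± 0.36 log2), MF(ALPHA)2 (2.88 ± 0.29), PUT4 (2.82 ± 0.17) and HXT6 (2.70 ± 0.23) against DIP5 (-3.42 ± 0.53), PYC1 (-2.75 ± 0.20), YHR033W (-2.73 ± 0.28), SPS4 (-2.57 ± 0.34) and ECM13 (-2.28 ± 0.25), with largest adjusted p = 6.19e-04. Of 6 MATalpha-specific genes, 4 were higher, 0 lower and 2 did not pass (5 and 0 adjusted over the list alone, camera adjusted p = 5.22e-06, adjusted p = 0.0440 with an estimated correlation). Of 9 galactose regulon genes, 0 were higher, 4 lower and 5 did not pass (1 and 4 adjusted over the list alone, camera adjusted p = 0.0014, adjusted p = 0.0440 with an estimated correlation). Of 25 glycolysis genes, 14 were higher, 1 lower and 10 did not pass (17 and 2 adjusted over the list alone, camera adjusted p = 5.99e-12, adjusted p = 0.0875 with an estimated correlation). Of 48 respiratory genes, 1 were higher, 26 lower and 21 did not pass (2 and 33 adjusted over the list alone, camera adjusted p = 6.76e-18, adjusted p = 0.0895 with an estimated correlation). The amino acid permease and nitrogen catabolite lists (each adjusted p = 0.0622) passed with the culture as a block (adjusted p = 0.0214 and adjusted p = 0.0223), but not with an estimated correlation as well (adjusted p = 0.188 and adjusted p = 0.523). With both, the galactose list did not pass either (adjusted p = 0.188). Of 5831 genes tested 522 passed, 182 higher and 340 lower, against 113 without wild type culture 1, 206 without wild type culture 2 and 866 without mutant 2.3b culture 2.

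In mot3 grr1-1 sin4 single hexose transporter genes had large values in both directions, and their list was not called (camera adjusted p = 0.285). The low-affinity transporter genes HXT1 and HXT3 were relatively higher in galactose than in glucose, and the high-affinity genes HXT6 and HXT7 and the hexokinase gene HXK1 were relatively lower. Values were TPO2 (3.62 ± 0.36 log2), HXT1 (3.04 ± 0.37), PHO3 (2.87 ± 0.38) and HXT3 (2.72 ± 0.40) against HXT7 (-4.03 ± 0.23), HXT6 (-3.65 ± 0.23), TMA10 (-2.93 ± 0.50), KNH1 (-2.87 ± 0.20) and HXK1 (-2.40 ± 0.31), with largest adjusted p = 7.60e-04. HIS3, which encodes an enzyme of histidine synthesis and often serves as a reporter, was relatively higher (1.58 ± 0.29, adjusted p = 0.0012), and GAL3, the galactose sensor gene, relatively lower (-1.26 ± 0.14, adjusted p = 1.93e-05). Of 27 glucose-repressed genes, 1 were higher, 12 lower and 14 did not pass (4 and 15 adjusted over the list alone, camera adjusted p = 3.96e-05, adjusted p = 0.166 with an estimated correlation). Of 25 glycolysis genes, 18 were higher, 4 lower and 3 did not pass (20 and 4 adjusted over the list alone, camera adjusted p = 6.74e-11, adjusted p = 0.159 with an estimated correlation). Of 48 respiratory genes, 3 were higher, 27 lower and 18 did not pass (3 and 29 adjusted over the list alone, camera adjusted p = 9.01e-09, adjusted p = 0.335 with an estimated correlation). Of 22 nitrogen catabolite genes, 1 were higher, 12 lower and 9 did not pass (1 and 13 adjusted over the list alone, camera adjusted p = 4.31e-04, adjusted p = 0.210 with an estimated correlation). Of 8 marker and reporter genes, 3 were higher, 0 lower and 5 did not pass (3 and 0 adjusted over the list alone, camera adjusted p = 0.0399, adjusted p = 0.166 with an estimated correlation), a call lost with the culture as a block (adjusted p = 0.0619). Of 5828 genes tested 979 passed, 362 higher and 617 lower. The count was 411 and 332 without its own culture 1 or 2, 334 and 463 without wild type culture 1 or 2, and 1639 without either culture of mutant 2.3b.

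In mot3 mit1-1 sin4, the hexose transporter genes HXT15 and HXT16 and the dehydrogenase gene DSF1 were relatively highest in galactose, although the hexose transporter list was not called (camera adjusted p = 0.187). They were followed by TDH1, a glyceraldehyde-3-phosphate dehydrogenase gene, and FLO11, while the carbonic anhydrase gene NCE103 and the general amino acid permease gene GAP1 were relatively lower. Values were HXT15 (4.44 ± 0.65 log2), HXT16 (3.98 ± 0.32), DSF1 (3.85 ± 0.33), TDH1 (3.28 ± 0.24) and FLO11 (2.96 ± 0.43) against NCE103 (-2.07 ± 0.28), GAP1 (-1.81 ± 0.20) and CHA1 (-1.63 ± 0.16), with largest adjusted p = 8.60e-04. Of 25 glycolysis genes, 21 were higher, 1 lower and 3 did not pass (21 and 1 adjusted over the list alone, camera adjusted p = 1.42e-30, adjusted p = 0.0076 with an estimated correlation). Of 16 phosphate genes, 6 were higher, 0 lower and 10 did not pass (12 and 0 adjusted over the list alone, camera adjusted p = 1.31e-10, adjusted p = 0.0432 with an estimated correlation). Of 9 galactose regulon genes, 0 were higher, 1 lower and 8 did not pass (0 and 1 adjusted over the list alone, camera adjusted p = 0.0038, adjusted p = 0.0445 with an estimated correlation). With the culture as a block and an estimated correlation, glycolysis passed (adjusted p = 0.0197) and the phosphate and galactose lists did not (adjusted p = 0.135 and adjusted p = 0.436). The MATalpha-specific list was called higher (camera adjusted p = 0.0464, adjusted p = 0.376 with an estimated correlation), and that call was lost with the culture as a block (adjusted p = 0.0740). Of 5810 genes tested 186 passed, 110 higher and 76 lower. The count was 97 without its own culture 2, 94 without either culture of mot3 grr1-1 sin4, 48 and 49 without wild type culture 1 or 2, and 542 without either culture of mutant 2.3b.

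Wild type was compared between media in the own-strain channel, to see the response to each shift. From raffinose to galactose, the GAL genes that import and break down galactose rose most, at GAL2 (11.03 ± 0.20 log2), GAL7 (10.65 ± 0.26), GAL1 (9.53 ± 0.13) and GAL10 (9.45 ± 0.24), together with the regulator genes GAL3 (4.15 ± 0.13) and GAL80 (1.89 ± 0.11). In raffinose GAL2 (6.201) and GAL10 (7.34) had a value on 1 of 2 arrays each, and GAL7 (6.46) was as low in the reference channel, so the size and order of these 3 rises are uncertain. TRP1, a neighbour of GAL3 on chromosome IV that encodes a tryptophan synthesis enzyme, rose by 5.27 ± 0.14, and respiratory genes rose too, among them the aconitase gene ACO1 (2.19 ± 0.20). HIS3 rose by 3.77 ± 0.25, and the largest adjusted p of the genes named so far was 3.19e-06. URA3 did not pass (-0.40 ± 0.21, adjusted p = 0.297). The largest decrease to hold without either culture was NUT2 (Mediator, -6.09 ± 0.44). Its reference channel fell too (-4.86), so no response of that size is shown. Of 11 galactose regulon genes, 10 were higher, 0 lower and 1 did not pass (10 and 0 adjusted over the list alone, camera adjusted p = 4.35e-19, adjusted p = 2.85e-05 with an estimated correlation). Of 48 respiratory genes, 34 were higher, 0 lower and 14 did not pass (42 and 0 adjusted over the list alone, camera adjusted p = 2.60e-24, adjusted p = 0.0489 with an estimated correlation). With the culture as a block as well, the respiratory list did not pass (adjusted p = 0.0501). Of 25 glycolysis genes, 10 were higher, 1 lower and 14 did not pass (13 and 1 adjusted over the list alone, camera adjusted p = 1.86e-07, adjusted p = 0.137 with an estimated correlation). Of 15 Mediator head and middle genes, 0 were higher, 3 lower and 12 did not pass (0 and 3 adjusted over the list alone, camera adjusted p = 0.0200, adjusted p = 0.343 with an estimated correlation). Of 6099 genes tested 452 passed, 256 higher and 196 lower. The split was 215 and 319 with median scaling and 356 and 379 as log ratios, and only 92 passed without wild type culture 1 and 152 without culture 2.

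From raffinose to glucose, the lists of respiration, storage carbohydrates and glucose-repressed genes were called lower in wild type. None was with an estimated correlation. PYC1, the carbonic anhydrase gene NCE103, the maltase gene MAL12 and the stress gene HSP12 fell, and TPO2, the purine synthesis gene ADE17, the malic enzyme gene MAE1 and the alpha-cell genes MF(ALPHA)2 and SAG1 rose. Values were TPO2 (4.31 ± 0.35 log2), ADE17 (4.28 ± 0.32), MF(ALPHA)2 (3.98 ± 0.28), SAG1 (3.44 ± 0.15) and MAE1 (3.35 ± 0.36) against PYC1 (-4.50 ± 0.14), TMA10 (-3.81 ± 0.38), NCE103 (-3.80 ± 0.21), MAL12 (-3.75 ± 0.28) and HSP12 (-3.64 ± 0.43), with largest adjusted p = 7.28e-06. The median of all genes stood at -0.167. Of 48 respiratory genes, 0 were higher, 46 lower and 2 did not pass (1 and 46 adjusted over the list alone, camera adjusted p = 5.78e-17, adjusted p = 0.162 with an estimated correlation). Of 27 glucose-repressed genes, 1 were higher, 21 lower and 5 did not pass (1 and 22 adjusted over the list alone, camera adjusted p = 8.15e-07, adjusted p = 0.182 with an estimated correlation). Of 20 trehalose and glycogen genes, 0 were higher, 18 lower and 2 did not pass (0 and 18 adjusted over the list alone, camera adjusted p = 1.32e-06, adjusted p = 0.228 with an estimated correlation). Of 137 ribosomal protein genes, 82 were higher, 1 lower and 54 did not pass (86 and 1 adjusted over the list alone, camera adjusted p = 1.44e-21, adjusted p = 0.182 with an estimated correlation). Of 6 MATalpha-specific genes, 6 were higher, 0 lower and 0 did not pass (6 and 0 adjusted over the list alone, camera adjusted p = 3.08e-07, adjusted p = 0.0072 with an estimated correlation). Of 9 core histone genes, 0 were higher, 9 lower and 0 did not pass (0 and 9 adjusted over the list alone, camera adjusted p = 6.18e-04, adjusted p = 0.216 with an estimated correlation). Of 5842 genes tested 2426 passed, 624 higher and 1802 lower, or 888 and 1215 with median scaling. The split was 314 and 877 without wild type culture 1, and 266 and 1440 without culture 2.

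Between galactose and glucose, the respiratory list was called higher in galactose, also with an estimated correlation. The glucose-repressed and stress lists were called higher only without it. The largest differences were GAL7 (10.87 ± 0.26 log2), GAL1 (9.68 ± 0.13), GAL3 (6.77 ± 0.13), TRP1 (5.26 ± 0.14) and TMA10 (5.17 ± 0.38) against ADE17 (-5.80 ± 0.32), TPO2 (-4.86 ± 0.35) and HXT1 (-3.87 ± 0.32), where HXT1 encodes the low-affinity hexose transporter of glucose-grown cells, with largest adjusted p = 8.89e-08. GAL7 and GAL3 averaged 6.24 and 6.42 in glucose, so the size of their differences is uncertain. The median of all genes stood at 0.193. Of 48 respiratory genes, 48 were higher, 0 lower and 0 did not pass (48 and 0 adjusted over the list alone, camera adjusted p = 1.32e-23, adjusted p = 0.0361 with an estimated correlation). Of 9 galactose regulon genes, 9 were higher, 0 lower and 0 did not pass (9 and 0 adjusted over the list alone, camera adjusted p = 6.49e-08, adjusted p = 0.0032 with an estimated correlation). Of 27 glucose-repressed genes, 23 were higher, 0 lower and 4 did not pass (23 and 0 adjusted over the list alone, camera adjusted p = 2.40e-07, adjusted p = 0.134 with an estimated correlation). Of 28 stress genes, 27 were higher, 0 lower and 1 did not pass (27 and 0 adjusted over the list alone, camera adjusted p = 5.45e-08, adjusted p = 0.286 with an estimated correlation). HIS3 differed by 2.95 ± 0.25 and HIS4, another histidine synthesis gene, by -2.77 ± 0.23. Of 5841 genes tested 2774 passed, 1944 higher and 830 lower, or 1264 and 1265 with median scaling. The split was 1106 and 474 without wild type culture 1, and 1539 and 311 without culture 2.

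The galactose response of each strain asks whether GAL genes respond in every mutant. Every GAL gene tested rose from raffinose to galactose in every strain: 6 of 6 in wild type and mutant 1.2, 5 of 5 in both triple mutants, and 4 of 4 in mutants 2.3a and 2.3b. GAL1 rose by 9.20 log2 in mutant 1.2, 8.13 in mutant 2.3a, 8.49 in mutant 2.3b, 8.74 in mot3 grr1-1 sin4 and 8.69 in mot3 mit1-1 sin4. HIS3 rose in each as well, by 4.33, 3.01, 2.33, 4.90 and 3.50 in that order. In galactose, the level of HIS3 in mot3 grr1-1 sin4 was above wild type (1.12 ± 0.25, adjusted p = 0.0031), though not past the threshold without its culture 1 (1.00, adjusted p = 0.0525) or wild type culture 2 (0.93, adjusted p = 0.0604). GAL3 was below wild type in galactose in mutant 2.3a (-0.98 ± 0.16, adjusted p = 6.67e-04) and mutant 2.3b (-0.98 ± 0.13, adjusted p = 4.00e-05), and the log ratio to the reference gave -0.53 and -0.50. In mutant 2.3a it was already lower in raffinose (-0.86, adjusted p = 0.0015). In mutant 1.2 it was lower in the own-strain channel alone (-0.69 ± 0.16, adjusted p = 0.0028, log ratio -0.15). GAL80, the repressor gene of the pathway, was below wild type in the same strains (-0.68 ± 0.14, adjusted p = 0.0042, and -0.80 ± 0.11, adjusted p = 6.80e-05), with log ratios of -0.40 and -0.50. In mutant 1.2 GAL80 was above wild type (0.43 ± 0.14, adjusted p = 0.0215, log ratio 0.54), though not past the threshold without wild type culture 2 (0.37, adjusted p = 0.0807). It was already higher there in raffinose (0.73, adjusted p = 0.0011). GAL1 was lower in mutant 2.3a (-1.46 ± 0.16, adjusted p = 8.96e-06) and mutant 2.3b (-1.24 ± 0.13, adjusted p = 3.78e-06) in the own-strain channel alone, with log ratios of 0.03 and 0.35. In mot3 mit1-1 sin4 it was lower in both (-0.76 ± 0.13, adjusted p = 0.0011, log ratio -0.76). The own-strain level of GAL10 was lower in all 5 mutants (-1.11, -2.02, -1.91, -1.40 and -1.05 in the order above), against log ratios of 0.69, 0.46, 0.38, 0.50 and -0.36. It did not pass in mot3 mit1-1 sin4 without wild type culture 1 (-1.048) or 2 (-1.055). GAL7 was lower in mutant 2.3b (-1.33 ± 0.26, adjusted p = 0.0016, log ratio -0.03) and mot3 grr1-1 sin4 (-1.002 ± 0.26, adjusted p = 0.0112, log ratio 1.05). In the latter it did not pass without its culture 1 (-0.79) or wild type culture 1 (-1.03) or 2 (-0.97). As log ratios outside galactose, HIS3 in raffinose was higher in mutant 2.3b (1.05 ± 0.20, adjusted p = 7.07e-04), and GAL3 in glucose was higher in mutant 1.2 (1.23 ± 0.12) and mot3 grr1-1 sin4 (1.30 ± 0.10, larger adjusted p = 4.33e-07). The low wild-type level of GAL3 in glucose (6.42) leaves the size uncertain.

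**Figure D3:**
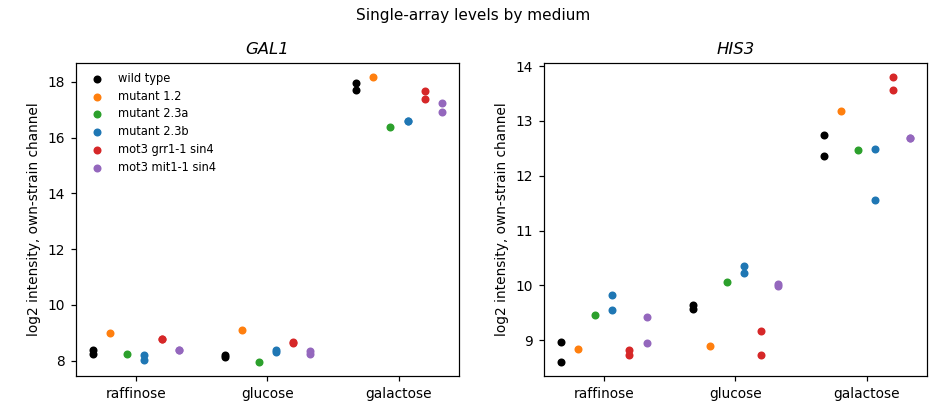
Points are single arrays, with the log2 intensity of the own-strain channel of GAL1 (left) and HIS3 (right) on the vertical axis and the medium on the horizontal axis, coloured by strain. Wild type GAL1 averages 17.84 in galactose against 8.31 in raffinose, and wild type HIS3 averages 12.55 against 8.79.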

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

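Own-channel GAL and HIS3 contrasts of mutants with wild type were chosen only after the results were seen. So were the tests below of chromosome III, cell type and the reference channel. Responses to a medium are listed here where the difference between strains itself passed. Galactose minus glucose differed from wild type at 522 genes in mutant 2.3b, led by AQR1 (3.69), TPO2 (3.45), MF(ALPHA)2 (2.88), DIP5 (-3.42), PYC1 (-2.75) and YHR033W (-2.73). AQR1 did not pass without mutant 2.3b culture 1 (3.31), wild type culture 1 (4.04) or culture 2 (3.33). It differed at 979 genes in mot3 grr1-1 sin4, led by TPO2 (3.62), HXT1 (3.04), AQR1 (2.98), HXT7 (-4.03), HXT6 (-3.65) and TMA10 (-2.93). AQR1 did not pass there without mot3 grr1-1 sin4 culture 1 (2.67), its culture 2 (3.29), wild type culture 1 (3.33) or culture 2 (2.63). In mot3 mit1-1 sin4 it differed at 186 genes, led by HXT15 (4.44), HXT16 (3.98), DSF1 (3.85), NCE103 (-2.07), TMA10 (-2.02) and GAP1 (-1.81). TMA10 did not pass without its own culture 1 (-1.84) or 2 (-2.21) or wild type culture 1 (-2.28) or 2 (-1.77). Nor did it without either culture of mot3 grr1-1 sin4 (-2.02). Counts without each culture are given above.

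In the own-strain channel, the difference between galactose and raffinose was smaller than in wild type for GAL1 in mutant 2.3a (-1.40), for GAL1 (-1.04), GAL7 (-1.66) and GAL80 (-1.18) in mutant 2.3b, for GAL2 in mot3 grr1-1 sin4 (-1.78), and for GAL1 (-0.84) and GAL2 (-2.23) in mot3 mit1-1 sin4. As log ratios, GAL80 in mutant 2.3b also passed (-0.84, adjusted p = 0.0012). GAL1 turned in mutants 2.3a (0.22) and 2.3b (0.60) and GAL2 in mot3 grr1-1 sin4 (0.86). The reference followed the own channel there, so these turns cannot decide. GAL7 in mutant 2.3b (-0.25) and GAL1 (-0.60) and GAL2 (-2.37) in mot3 mit1-1 sin4 kept their direction without passing, GAL2 with a larger standard error (0.77 against 0.25). In raffinose GAL2 had a value on 1 array in wild type (6.201) and 1 in mot3 grr1-1 sin4 (7.91), and its galactose level there did not differ (-0.07, adjusted p = 0.8035), so weaker activation is not shown. In mot3 mit1-1 sin4, 1.49 of the GAL2 difference lies in raffinose against the same wild-type array, and -0.74 in galactose. GAL1 no longer passed in mutant 2.3a without wild type culture 2 (-1.20), or in mutant 2.3b without its culture 1 (-0.93) or wild type culture 2 (-0.84). GAL7 in mutant 2.3b did not pass without its culture 1 (adjusted p = 0.107), either culture of mot3 grr1-1 sin4 (adjusted p = 0.1002), or wild type culture 1 (adjusted p = 0.332) or 2 (adjusted p = 0.166), and GAL80 did not without wild type culture 1 (-0.95, adjusted p = 0.0547). GAL2 in mot3 grr1-1 sin4 did not pass without its culture 2 (-1.73) or wild type culture 2 (-1.62). GAL1 in mot3 mit1-1 sin4 did not pass without its culture 1 (-0.67) or 2 (-1.01), wild type culture 1 (-1.04) or 2 (-0.64), or either culture of mot3 grr1-1 sin4 (adjusted p = 0.0775).

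Genes of chromosome III were higher in mutants 2.3a and 2.3b, with a median that depended on neither the normalization (0.81 with median centring and no background correction) nor the mating-type genes (0.83 without them). The higher of the medians of the triple mutants was 0.11, which argues against loss of MOT3 and SIN4 function as the cause. On each of the 9 arrays both arms were raised, with a lowest arm median of 0.63. An extra copy of the chromosome may therefore explain the pattern, and no value of DNA content was measured.

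MATALPHA1 and MATALPHA2 spots had values on all arrays, and HMRA1, in no comparison, on 9 of 9 of mutants 2.3a and 2.3b. HMRA1 had 0 of 6 in wild type and 1 of 15 in other mutants. The MATa list exceeded the MATalpha list by at least 5.52 log2 on each array of 2.3a and 2.3b. But HMLALPHA2 was higher (0.54 and 0.40). Haploid-specific genes near wild type (lower median -0.15) argue against a diploid with both mating types. MATalpha-specific medians of at most 9.5% of wild type over media, and -2.23 log2 on any array, argue against an equal mixture with MATa cells. A MATa genotype here, against a MATalpha wild type, may account for most of the pattern, untested in DNA.

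The reference channel of GAL1 was 4.59 log2 higher on wild-type galactose arrays than on raffinose arrays. Over genes that differ between galactose and glucose in wild type, the reference followed the own channel with a slope of 0.104, which argues against reference RNA from the medium of each array. The reference channel of LEU2 was 1.82 higher in the mutants than in wild type on raffinose arrays, so bleed-through from very bright own-strain spots may contribute. The share would not be fixed, since it differed 11.2-fold between GAL1, GAL2, GAL7, GAL10 and LEU2. What else raises the reference is open.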

How the results depend on the processing

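The alternatives that left out chromosome III and the mating-type lists, chose a reference column by its blank spots, exchanged culture numbers, used the log ratio between wild-type media, or repeated the GAL comparisons were chosen only after the data were seen, and the others before. Over these alternatives, 8494 values of named genes that had passed were recomputed, so gained calls are not counted: 8004 kept their direction and side of the threshold, 459 kept their direction but no longer passed, and 31 turned. None changed without background correction (460 values), without dim probes (403) or with quantile scaling (166), and 562 of 578 held with median centring. Leaving out a culture kept 4707 of 5087 and turned none. Where it left an arm with 1 culture, that culture is assumed to vary like the other groups, and counts rose as well as fell. Of 636 counts and other main values, 505 held and 131 moved by more than 1.5 times or changed their call. Every contrast with wild type rests on 2 wild-type cultures, and 67 to 535 spots per array were blank. The cause of the changes below was not tested.

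Counts without each culture in turn, averaged over media, ranged from 798 to 1760 in mutant 2.3a, 1588 to 2600 in mutant 2.3b, 1510 to 2945 in mot3 grr1-1 sin4, 471 to 1580 in mot3 mit1-1 sin4 and 1412 to 2808 between the triple mutants. In galactose the ranges were 537 to 1353 in mutant 2.3a, 1135 to 2617 in mutant 2.3b, 1247 to 2603 in mot3 grr1-1 sin4 and 442 to 1743 in mot3 mit1-1 sin4. In glucose they were 484 to 1424, 803 to 1551, 878 to 2341 and 268 to 1162 in the same order. In raffinose they were 1011 to 2399, 1163 to 2323, 1057 to 2521 and 416 to 1540. Differences between galactose and glucose ranged from 113 to 866 in mutant 2.3b, 332 to 1639 in mot3 grr1-1 sin4 and 48 to 542 in mot3 mit1-1 sin4. Wild-type counts ranged from 92 to 152 for galactose over raffinose, 1191 to 1706 for glucose over raffinose and 1580 to 1850 for galactose over glucose. Label genes whose call changed ranged, in mutant 1.2, from -0.273 to -0.237 (GRR1) and -0.313 to -0.221 (MIT1). In mot3 grr1-1 sin4 they ranged from -0.259 to -0.200 (GRR1) and -0.346 to -0.210 (MIT1), and in mot3 mit1-1 sin4 from -0.317 to -0.239 (MOT3).

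With each strain's log ratio against 0, wild-type variation drops out but any wild-type gap to the reference stays, so strain differences are not tested. The counts were 2934 in mutant 2.3a, 4029 in mutant 2.3b, 3983 in mot3 grr1-1 sin4 and 3229 in mot3 mit1-1 sin4. GRR1 no longer passed in mutant 1.2 (-0.093) and mot3 grr1-1 sin4 (-0.068), nor MOT3 in mot3 mit1-1 sin4 (-0.057). GRR1 passed in mutant 2.3b (0.186) and mot3 mit1-1 sin4 (0.287). Against 0, these genes turned: FUS1 in mutant 1.2 (0.092), GAL3 (0.113), HXT2 (-0.483), HXT7 (-0.147), HXT6 (-0.161), GPP2 (-0.105), HTA1 (-0.273), HTA2 (-0.380) and HHT2 (-0.301) in mutant 2.3a, and GAL3 (0.247), YOX1 (0.296), CLN2 (0.10) and CLB6 (0.138) in mutant 2.3b. So did SAG1 (0.030) in mot3 grr1-1 sin4, and GAL1 (1.366), HHF1 (-0.114), HHT2 (-0.288) and HHF2 (-0.134) in mot3 mit1-1 sin4. With the authors' tables, GAL3 in mutant 1.2 turned (-0.132), and MIT1 passed in mutant 1.2 (-0.373) and mot3 grr1-1 sin4 (-0.360), as it did in the latter without dim probes (-0.278). The authors' table of a medium tested fewer genes and gave, in galactose, 422 in mutant 2.3a, 1372 in mutant 2.3b, 1372 in mot3 grr1-1 sin4 and 448 in mot3 mit1-1 sin4. In raffinose it gave 1263 in mutant 1.2, 878, 1154, 1260 and 441 in the same order of strains. With the 10 arrays of a medium alone, mot3 mit1-1 sin4 had 757 genes in galactose and 616 in raffinose, and mutant 2.3a had 1377 in glucose and 1145 in raffinose.

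Pairing across strains rests on the culture number alone. Residuals of cultures with the same number correlated between -0.15 and 0.38, with 1 of 6 values over 0.1. With the replicate block the counts averaged over media were 3339, 1339, 2541, 2569, 1130 and 2382, and NUT1 (adjusted p = 0.0597) and RPS28B (adjusted p = 0.0507) in mutant 2.3a and PRM8 (adjusted p = 0.0551) in mot3 mit1-1 sin4 no longer passed. Blocking by culture within strains gave 715, 1373 and 272 genes for the differences between galactose and glucose. Leaving out chromosome III and the mating-type lists gave 1193 genes in mutant 2.3a and 2346 in mutant 2.3b. Reference columns chosen by their blanks gave 1357 and 2531, and exchanged culture numbers gave 1105 for mot3 mit1-1 sin4 and 2279 between the triple mutants. The log ratio gave 735 genes for galactose over raffinose in wild type. The reference channel of all 10 arrays per medium was near 0 with the other sign for TPO2 (-0.043), MAE1 (-0.033) and PYC1 (0.045) for glucose over raffinose and TMA10 (-0.009) for galactose over glucose, where that of the wild-type arrays alone gave 0.262, 0.239, 0.176 and 0.106. As log ratios these GAL values turned: in mutant 1.2 the GAL10 level (0.687), in mutant 2.3a the GAL1 response (0.218) and the levels of GAL1 (0.034), GAL2 (5.08e-04) and GAL10 (0.462), in mutant 2.3b the GAL1 response (0.597) and the levels of GAL1 (0.355), GAL2 (0.232) and GAL10 (0.381), and in mot3 grr1-1 sin4 the GAL2 response (0.859) and the levels of GAL7 (1.046) and GAL10 (0.499).

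With an estimated correlation, camera called 0 lists in each strain, between the triple mutants and in the galactose minus glucose difference of mot3 grr1-1 sin4, where the preset value called 21, 19, 21, 15, 15, 17 and 11. It called 2 for the difference in mutant 2.3b and 3 in mot3 mit1-1 sin4, and 2, 1 and 3 in wild type. With the culture as a block as well, these were 0, 1, 1, 1 and 3. By fry, 23 lists passed in mot3 grr1-1 sin4, 23 for glucose over raffinose and 22 for galactose over glucose. Without dim probes the correlations between strains were 0.538 (mutants 1.2 and 2.3a), 0.574 (1.2 and 2.3b), 0.639 (1.2 and mot3 grr1-1 sin4), 0.915 (2.3a and 2.3b), 0.741 (2.3a and mot3 grr1-1 sin4), 0.510 (2.3a and mot3 mit1-1 sin4) and 0.761 (2.3b and mot3 grr1-1 sin4).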
